A study of Mus musculus with 17 samples.

How the data were processed

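Serum microRNA (miRNA) was measured by real-time PCR in 17 mice: 3 healthy wild-type FVB/N mice, 7 AT-ATX mice, which carry an Autotaxin transgene, without tumors and 7 AT-ATX mice with spontaneous tumors. Autotaxin is a secreted enzyme that makes the signaling lipid lysophosphatidic acid. Per the labels' protocols, blood was taken at necropsy and spun, total RNA was extracted from 50 µL of serum, cDNA was made with a universal kit, and SYBR Green PCR was run for 40 cycles on 2 ready-made serum miRNA panel plates. Each sample is named as 1 mouse in the labels. The labels give no batch, and the meaning of the number in each transgenic animal's label is not stated. The label of tumor replicate 5 carries a question mark, and the sample was kept in its labelled group.

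The deposited values are quantification cycles (Ct) per assay and sample, not normalized to a reference RNA per the name of the file. A lower Ct means more template, and 1 cycle is close to a factor of 2 in amount. How the authors set the threshold, calibrated between plates and chose the detection limit is not given in the sources used here. The table holds 365 assays, of which 8 are controls and 357 are miRNAs, 317 named for mouse and 40 for rat. Of the rat assays, 20 share their name with a mouse assay, and both target near-identical RNAs, so they are not independent measurements. No value lies at or above 37, and empty cells were taken as not detected. The last decimals of the values split the assays into sets of 245 and 120 in 13 samples, with 0 assays placed differently between samples. These sets were taken as the 2 plates. The other 4 samples, tumor-free replicates 4, 5 and 7 and tumor replicate 1, had 1 ending only. Whether this marks a separate run was not tested. No pair of samples held the same values: the smallest SD of the difference between 2 samples was 0.665 cycles.

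The level of a miRNA was the mean Ct of the 252 miRNA assays detected in all 17 samples minus its own Ct, on a log2 scale, so that a difference of 1 is a change of 2 times under full PCR efficiency. Such levels are relative to the mean of the panel and do not give the amount per volume of serum. An assay was tested if detected in at least 2 wild-type mice, 5 tumor-free mice and 5 tumor mice. This left 338 assays and set aside 19. The tested assays held 160 missing values, in 86 assays. All 3 groups entered 1 fit in limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the 338 assays within each of the 3 comparisons and a threshold of 0.05. Every adjusted p given for a single miRNA comes from this limma fit.

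The 3 measures per sample (assays detected, mean Ct of the 252 assays, and the hemolysis index, the Ct of miR-23a-3p minus that of miR-451a), the miRNA lists and the control assays were compared by exact two-sided permutation tests of the difference of group means. Adjustment covered the 9 tests of sample measures, the 51 tests of lists and the 24 tests of control assays separately. With 3 wild-type mice against 7, no exact p can lie below 0.00833, and with 7 against 7 none can lie below 0.000583. Detection was compared by Fisher's exact test. Correlations within groups were computed over 17 samples after each group's mean was taken off, with permutation p from random reorderings within groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

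Lists of miRNAs were fixed before the data were examined, from textbook knowledge of where these miRNAs are abundant or how they are encoded. They covered red blood cell, liver, platelet, lymphocyte and other white blood cell, myeloid, skeletal and heart muscle, endothelium and smooth muscle, epithelium, brain and neuron, the mir-17-92 and paralogous clusters, the let-7, mir-30, mir-29 and mir-34 families, miRNAs often raised in tumors, the imprinted Dlk1-Dio3 cluster and the Sfmbt2 intron cluster. These 17 lists had at least 3 tested members. A list for the pancreas and one for early embryo clusters had fewer and were not tested. A list's level in a sample was the mean over its tested members, with undetected members set to a Ct of 37. Lists overlap: 7 of 13 members of the tumor list, 5 of 14 of the mir-17-92 list and 4 of 7 of the myeloid list lie on another list, and 0 of 11 liver members do. The miRNAs named were the 10 with the smallest p where fewer than 10 passed, otherwise the first 10 of each direction, the most abundant members of each list, and miR-451a, miR-16-5p, miR-23a-3p, miR-122-5p, miR-21a-5p, miR-150-5p, miR-155-5p, miR-223-3p and miR-34a-5p. Members that passed only over their own list, the remaining miRNAs that passed and the miRNAs of gene clusters were named after their values were seen. Adjustment over a list alone was made within each list and comparison, with none across lists or comparisons. Members that passed only that way are weaker findings than those that passed over all assays.

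Alternatives fixed before the data were examined were 5 other scalings (median, 4 reference miRNAs, quantile, raw Ct and spike-ins), a detection limit of Ct 35, other filters and treatments of missing values, a fit of only the 2 groups compared, trend and robust variance, exact permutation per assay, the hemolysis index as a covariate, the number in the animal label as a random block, and leaving out each sample. Scaling per plate set, leaving out both samples of low U6 Ct, leaving samples out for the control assays, the raw, spike-in and hemolysis settings for the lists, and the other scalings of the gene clusters and of the relations with the hemolysis index were added after seeing the data. List differences at equal hemolysis index were tested by permuting, among the samples of the 2 groups, the residuals of a fit with these groups merged, and adjusted over 51 tests. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly GRCm38.p6, used only for names and order: 264 of 300 tested mouse assays matched 1 gene, 27 several and 9 none.

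The procedure was tested on simulated data with the spread of the real samples, in which 60 of 338 assays carried a known change. Noise was drawn independently for each assay on scaled levels, so correlation between assays and the scaling itself were not simulated. The shares that follow hold for such data and may differ for real serum. In the comparison of tumor and tumor-free mice, 10.7% of changes of log2 1, 77.5% of log2 2 and 95.8% of log2 3 were recovered. For tumor-free against wild-type mice these shares were 1.08%, 56.1% and 86.5%, and for tumor against wild-type mice 0.917%, 55.8% and 84.8%. False calls made up 6.57%, 13.3% and 8.33% of all calls at log2 1 in the same order of comparisons, and 4.13% to 5.77% at log2 2 and 3. Real-time PCR gives no read depth, and the number of mice limits the precision.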

Results

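Serum from 17 mice was profiled on a panel of 357 miRNA assays and 8 control assays. The design addressed which circulating miRNAs differ with the Autotaxin transgene and which differ with spontaneous tumors among transgenic mice. Between 312 and 356 miRNA assays were detected per sample, and 252 were detected in all 17 mice. The most abundant included miR-451a and miR-16-5p of red blood cells, miR-122-5p of hepatocytes and miR-21a-5p.

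The serum samples were first compared for amount and for release of red blood cell RNA. Tumor mice had 337.4 ± 14.6 (SD, n = 7) assays detected, tumor-free transgenic mice 346.6 ± 11.1 (n = 7) and wild-type mice 347.3 ± 7.51 (n = 3). The mean Ct of the shared assays was 29.8 ± 1.18, 29.4 ± 0.83 and 28.4 ± 1.50 in the same order. The hemolysis index was 3.97 ± 1.97, 4.38 ± 0.84 and 5.61 ± 2.07 cycles. None of the 9 exact permutation tests of these measures passed after adjustment, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.48. The index differed by -0.41 (tumor against tumor-free), -1.23 (tumor-free against wild type) and -1.63 (tumor against wild type). With miR-451a set against the panel mean instead, these differences were 0.065, -0.49 and -0.43. The index thus also follows miR-23a-3p of the myeloid list, and its group differences need not reflect lysis.

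**Figure D1:**
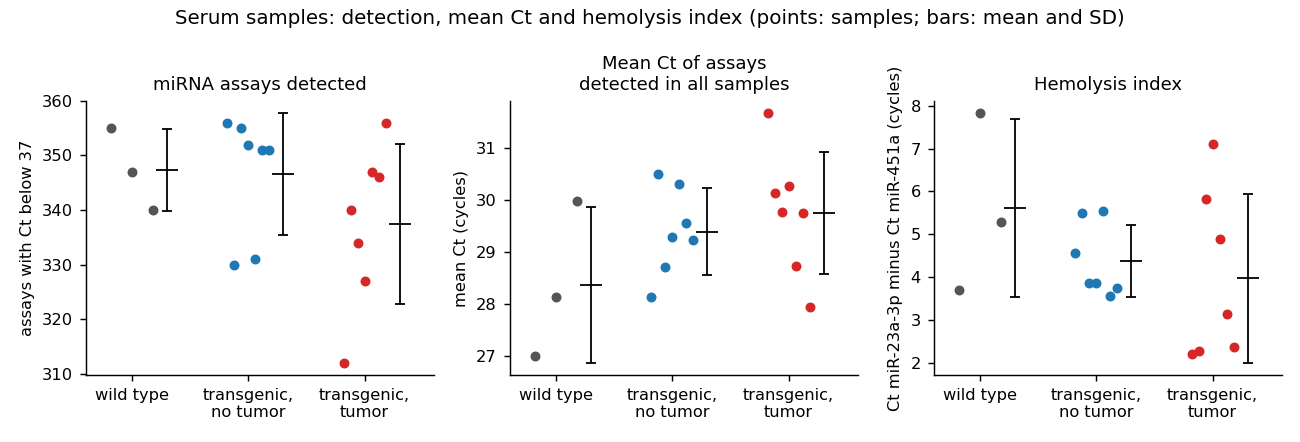
Number of miRNA assays detected, mean Ct of the assays detected in all samples (cycles) and hemolysis index (cycles) for each mouse, by group, with bars for mean and SD. The groups overlap in all 3 measures, and the hemolysis index of tumor mice (3.97 ± 1.97) spreads more widely than that of tumor-free transgenic mice (4.38 ± 0.84).

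Levels relative to the panel mean went with the hemolysis index in 11 of 17 lists. Over the 17 mice, with group means taken off, the level of the red blood cell list without miR-451a rose with the hemolysis index (r = 0.89, permutation p = 0.00044, adjusted p = 0.00221 over 17 lists; rho = 0.87, permutation p = 0.00047; r = 0.87 without the 2 farthest samples). The mir-17-92 list did so too (r = 0.94, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 8.5e-05; rho = 0.87, permutation p = 9e-05; r = 0.89 without the 2 farthest). The let-7 family (r = 0.85, permutation p = 0.00237, rho = 0.80, permutation p = 0.00535, r = 0.79 without the 2 farthest) and the mir-30 family (r = 0.77, permutation p = 0.00173, rho = 0.75, permutation p = 0.00586, r = 0.65 without the 2 farthest) followed. The platelet list ran the opposite way (r = -0.90, permutation p = 1e-05, rho = -0.95, permutation p = 1e-05, r = -0.81 without the 2 farthest), as did the endothelium and smooth muscle list (r = -0.88, permutation p = 0.00052, rho = -0.82, permutation p = 0.00246, r = -0.79 without the 2 farthest). So did the Dlk1-Dio3 list (r = -0.81, permutation p = 0.00435, rho = -0.79, permutation p = 0.00537, r = -0.82 without the 2 farthest), the skeletal and heart muscle list (r = -0.74, permutation p = 0.00258, rho = -0.67, permutation p = 0.00885, r = -0.70 without the 2 farthest), the mir-29 family (r = -0.72, permutation p = 0.0012, rho = -0.72, permutation p = 0.00158, r = -0.70 without the 2 farthest) and the mir-34 family (r = -0.69, permutation p = 0.00633, rho = -0.62, permutation p = 0.019, r = -0.54 without the 2 farthest). Over all 17 mice the liver list was less closely related (r = -0.57, permutation p = 0.0256, adjusted p = 0.0396; rho = -0.50, permutation p = 0.0499, adjusted p = 0.0723), and r was -0.39 without the 2 farthest samples, so the relation rests in part on them. Within the tumor-free mice alone, however, r was -0.92, and within the tumor mice it was -0.39. The other 6 lists did not pass: r was -0.18 (lymphocyte and other white blood cell), -0.13 (myeloid), -0.40 (epithelium), 0.23 (brain and neuron), -0.16 (often raised in tumors) and -0.53 (Sfmbt2). Levels relative to the panel mean must fall in some miRNAs when they rise in others, and miR-24-3p of the platelet list is encoded beside miR-23a-3p of the index. Raw Ct and spike-ins, chosen after the data were seen, are free of that centring, and with them 0 of 17 lists passed (smallest adjusted p 0.242 and 0.276). There r was 0.44 and 0.45 for the red blood cell list, 0.43 and 0.45 for the mir-17-92 list and -0.41 and -0.43 for the platelet list. It changed less for the skeletal and heart muscle list (-0.64 with both, permutation p = 0.0164 and 0.0171). The same held for the Dlk1-Dio3 list (-0.63 and -0.64, permutation p = 0.0285 and 0.0325). After adjustment these relations passed only for levels relative to the panel.

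Among transgenic mice, the question was which miRNAs differ with tumors. miR-802-5p, abundant in liver, fell to -1.31 ± 0.64 (SD, n = 7) from 0.68 ± 0.61 (n = 7) in tumor-free mice, a log2 difference of -1.99 (SE 0.37, 3.98-fold lower, adjusted p = 0.0105), and all 7 tumor mice lay below all tumor-free mice. The rat assay of the same name gave -2.15 (SE 0.47, adjusted p = 0.02). miR-192-3p, the minor arm of a hairpin expressed in liver and gut, fell by 1.86 (SE 0.37, adjusted p = 0.0128), and miR-455-3p, encoded in an intron of a collagen gene, fell by 2.67 (SE 0.58, 6.37-fold lower, adjusted p = 0.02), each with 6 of 7 tumor mice below all tumor-free mice. miR-339-3p was the only miRNA that passed in the other direction, with a log2 difference of 1.15 (SE 0.28, 2.22-fold higher, adjusted p = 0.0428) and all 7 tumor mice above all tumor-free mice.

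In all, 5 of 338 assays passed between tumor and tumor-free mice, 1 higher and 4 lower, and 57 had an unadjusted p under 0.05, 27 higher and 30 lower. The 5 next by p did not pass: miR-1900 differed by -2.39 (adjusted p = 0.053), miR-322-5p by 1.34 (0.0649), miR-31-3p by -1.63 (0.0843), miR-489-3p by 3.06 (0.115) and miR-31-5p by -1.43 (0.115). The hepatocyte miRNA miR-122-5p stood at 6.38 ± 1.43 in tumor mice and 8.01 ± 0.60 in tumor-free mice, a difference of -1.63 (adjusted p = 0.123). miR-21a-5p, often raised in tumors, differed by 0.89 (adjusted p = 0.135). Of the blood cell miRNAs, miR-223-3p of neutrophils differed by 0.68, miR-16-5p by 0.42, miR-23a-3p by 0.47, miR-451a by 0.06, and the lymphocyte miRNAs miR-150-5p and miR-155-5p by -0.65 and -0.68 (adjusted p from 0.429 to 0.931). miR-34a-5p differed by 0.19 (adjusted p = 0.842). With reference miRNAs, raw Ct or spike-ins as the scaling, 0 assays passed in limma (42, 17 and 14 at an unadjusted p under 0.05), and exact permutation per assay gave 0 (57 unadjusted, smallest adjusted p 0.0591). miR-802-5p and miR-192-3p passed without any 1 of the 17 mice, but miR-455-3p was kept in 13, the rat miR-802-5p in 12 and miR-339-3p in 6 of these 17 fits. miR-455-3p was also lost with a limit of Ct 35, and miR-339-3p with trend and robust variance. The count was 2 without tumor-free replicate 1 or 6 or tumor replicate 3 or 4, 3 without tumor-free replicate 3, 9 without tumor-free replicate 2, 10 without tumor replicate 5 and 8 without tumor replicate 7.

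**Figure D2:**
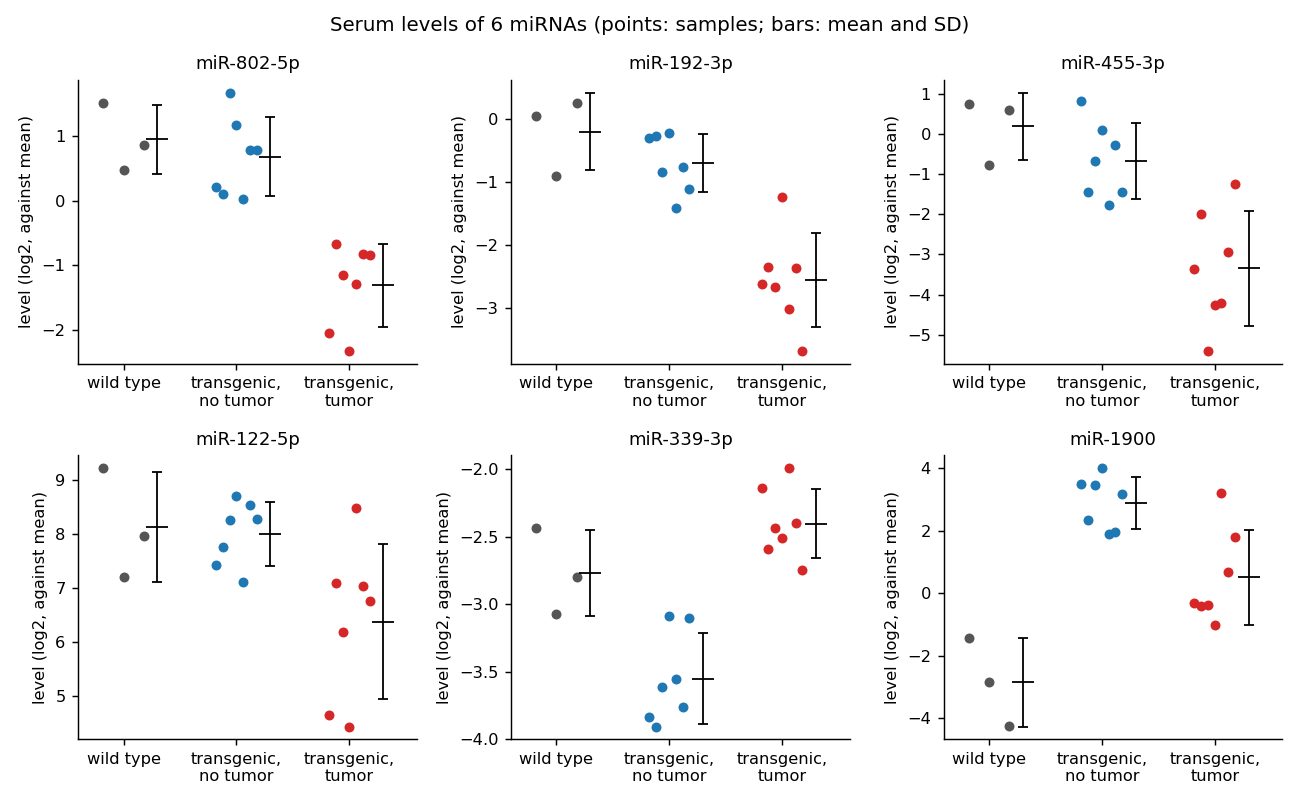
Level (log2, against the mean of the assays detected in all samples) of 6 miRNAs in each mouse, by group, with bars for mean and SD. miR-802-5p of all 7 tumor mice lies below all tumor-free mice, miR-339-3p of all 7 lies above them, and miR-1900 of all 7 tumor-free mice (2.90 ± 0.83) lies above all wild-type mice (-2.85 ± 1.41).

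Grouped by tissue, the liver list had the largest difference below 0, which did not pass after adjustment. Its mean level was 1.26 ± 0.50 (SD, n = 7) with tumors and 2.02 ± 0.50 (n = 7) without, a difference of -0.76 (exact permutation p = 0.0181, adjusted p = 0.184), with 9 of 11 members below 0. Of its members 1, miR-802-5p, passed over all assays, and 5 passed, all lower, adjusted over the list alone: miR-802-5p, miR-122-5p, miR-192-5p (-0.94), miR-194-5p (-1.39) and miR-455-5p (-1.01). The epithelium list, which includes the miR-200 family, differed by -0.67 (exact permutation p = 0.0542), with 0 of 9 members above 0, 0 passing over all assays and 1 lower, miR-31-5p, adjusted over the list alone. The brain and neuron list differed by 0.54 (exact permutation p = 0.00699, adjusted p = 0.184), with 0 of 6 members passing and 1 higher, miR-132-3p (1.22), adjusted over the list alone. The myeloid list differed by 0.42 (exact permutation p = 0.0728), with 0 of 7 members passing and 2 higher, miR-21a-5p and miR-322-5p, adjusted over the list alone.

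The list of miRNAs often raised in tumors did not move 1 way in tumor mice. Its difference was -0.15 (exact permutation p = 0.3) while the median of its members was 0.14, and it was 0.29 with a detection limit of Ct 35. None of its 13 members passed over all assays. Adjusted over the list alone, 3 were higher, miR-21a-5p, miR-210-3p (1.02) and miR-10b-5p (1.16), and 3 were lower, miR-182-5p (-1.78), miR-31-5p and miR-203-3p (-0.91). The other lists differed by 0.40 (red blood cell), 0.08 (platelet), -0.35 (lymphocyte and other white blood cell), -0.35 (skeletal and heart muscle), -0.04 (endothelium and smooth muscle), 0.24 (mir-17-92), -0.46 (let-7), -0.38 (mir-30), -0.01 (mir-29), 0.29 (mir-34), 0.87 (Dlk1-Dio3) and 0.13 (Sfmbt2), with no member passing over all assays or adjusted over the list alone. Without each sample in turn several of these spread widely: 0.18 to 0.62 (red blood cell), 0.015 to 0.20 (platelet), -0.58 to -0.19 (white blood cell), 0.038 to 0.43 (mir-17-92), -0.67 to -0.28 (let-7), -0.58 to -0.27 (mir-30), 0.029 to 0.51 (mir-34) and 0.60 to 1.08 (Dlk1-Dio3). Of the 17 lists 0 passed the exact permutation test after adjustment, and 2 had an unadjusted p under 0.05. At equal hemolysis index, a setting chosen after the data were seen, 0 of 51 list tests passed. There the red blood cell list, which holds 1 assay of the index, differed by 0.60 (permutation p = 0.0042), the brain and neuron list by 0.56 (permutation p = 0.00575) and the liver list by -0.83 (permutation p = 0.0069), all at adjusted p = 0.0704, the mir-17-92 list by 0.40 (permutation p = 0.0127, adjusted p = 0.0925), and the platelet list turned to -0.012.

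The comparison of tumor-free transgenic with wild-type mice concerned the transgene in the absence of tumors. miR-1900 stood far apart: its level was 2.90 ± 0.83 (SD, n = 7) in tumor-free transgenic mice and -2.85 ± 1.41 (n = 3) in wild-type mice, a log2 difference of 5.74 (SE 0.79, 53.5-fold higher, adjusted p = 0.000198). All 7 transgenic mice lay above all wild-type mice, and the call was kept without any 1 of the 17 mice, with differences from 5.01 to 6.44. The call was lost with raw Ct (adjusted p = 0.105), spike-ins (adjusted p = 0.0876) and exact permutation (adjusted p = 0.0828). The last leaves little room to pass, since no exact p against 3 wild-type mice can lie below 0.00833 and 338 assays were tested. miR-196b-5p, encoded in a Hox gene cluster, fell by 2.46 (SE 0.54, 5.49-fold lower, adjusted p = 0.0357), with all 7 below all wild-type mice. This call was kept in 6 of 13 alternatives and lost with the median, reference miRNAs, raw Ct, missing values set to Ct 37 under either filter, trend and robust variance, and exact permutation.

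These were the 2 of 338 assays that passed, 1 higher and 1 lower, and 76 had an unadjusted p under 0.05. The 8 next by p did not pass. They were miR-500-3p at 1.74 (adjusted p = 0.0509), the rat assay miR-352 at -3.30 (0.0696), miR-503-5p at 2.28 (0.072), the rat assay miR-338-3p at 2.48 (0.072), miR-186-3p at -2.15 (0.0825), miR-146a-5p at 2.32 (0.0899), miR-499-5p of muscle at 3.09 (0.0975) and miR-33-5p at 2.40 (0.132). Of the miRNAs named in each comparison, miR-155-5p differed by 2.10 (adjusted p = 0.141), miR-223-3p by 1.28, miR-16-5p by -1.32, miR-150-5p by 1.41, miR-34a-5p by 0.79, miR-23a-3p by 0.73, miR-21a-5p by 0.31, miR-451a by -0.49 and miR-122-5p by -0.12 (adjusted p from 0.187 to 0.909). Raw Ct gave 0 calls in limma (63 at an unadjusted p under 0.05), exact permutation per assay gave 0 (85 unadjusted, smallest adjusted p 0.0828), the median, reference miRNA and quantile scalings gave 1 each, and spike-ins gave 0 higher and 2 lower, 1 of them miR-196b-5p. The count was 9 without wild-type replicate 1 and 1 without wild-type replicate 2 or 3 or without tumor-free replicate 2, 3, 5, 6 or 7, and miR-196b-5p lost its call in these last 7 cases.

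The directions of many lists against wild-type mice depended on the scaling. The median log2 difference of all assays was 0.03 in this comparison and 0.19 in that of tumor with wild-type mice, but -1.07 and -1.22 with raw Ct, -1.28 and -1.18 with spike-ins and 0.54 and 0.37 with reference miRNAs. The directions given are therefore relative to the mean of the panel. With raw Ct and spike-ins the platelet, white blood cell, endothelium, Sfmbt2, mir-29 and mir-34 lists turned below 0 against wild type in at least 1 comparison, as did the epithelium, Dlk1-Dio3 and tumor lists for tumor-free mice and the myeloid and brain lists for tumor mice. With reference miRNAs the liver, myeloid and brain lists turned above 0 for tumor-free mice. The epithelium and tumor lists did so for tumor mice, the last also with the median. A difference of the reference miRNAs themselves between groups would shift every level under this scaling. Turns and lost calls under it therefore need not reflect the lists or miRNAs concerned. Between tumor and tumor-free mice the median was 0.14, against -0.24, -0.01 and -0.16 with the same 3 scalings. In that comparison the platelet, mir-17-92, mir-34 and Sfmbt2 lists turned below 0 with raw Ct and with reference miRNAs, the platelet and Sfmbt2 lists also with spike-ins, and the endothelium and mir-29 lists turned above 0 with the median.

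By list, no difference between tumor-free transgenic and wild-type mice passed after adjustment. The hemolysis index differed by -1.23 cycles (exact permutation p = 0.25). The mir-30 family differed by -0.78 (exact permutation p = 0.00833, adjusted p = 0.184), with 7 of 7 members below 0, 0 passing over all assays and 2 lower, miR-30a-5p and miR-30e-5p, adjusted over the list alone. The let-7 family differed by -0.89 (exact permutation p = 0.05), with 0 members passing either way. The mir-29 family differed by 1.14 (exact permutation p = 0.0167, adjusted p = 0.184) but by -0.09 with spike-ins, with 0 of 3 members passing over all assays and 1 higher, miR-29a-3p (1.40), adjusted over the list alone. The muscle list differed by 2.23 (exact permutation p = 0.0917), with 6 of 6 members above 0, 0 passing over all assays and 1 higher, miR-499-5p, adjusted over the list alone. The white blood cell list differed by 0.61 (exact permutation p = 0.0667) but by -0.41 with raw Ct and -0.62 with spike-ins, with 0 passing over all assays and 2 higher, miR-155-5p and miR-146a-5p, adjusted over the list alone. Tumor-free replicate 7 stood far from its group in both, and without it they differed by 1.78 and 1.92 and the list by 0.45. The liver list differed by -0.25, but by 0.24 with reference miRNAs. At equal hemolysis index these differences were -0.55 (mir-30, permutation p = 0.0087, adjusted p = 0.0739), -0.38 (let-7), 0.80 (mir-29), 1.07 (muscle), 0.54 (white blood cell) and -0.46 (liver), and the platelet and endothelium lists turned to -0.15 and -0.33.

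The remaining lists had no member passing over all assays or adjusted over the list alone. They differed from wild type by -0.87 (red blood cell), 0.13 (platelet), -0.04 (myeloid), 0.16 (endothelium and smooth muscle), 0.49 (epithelium), -0.13 (brain and neuron), -0.73 (mir-17-92), 1.06 (mir-34, but -0.17 with spike-ins), 0.11 (often raised in tumors), 1.02 (Dlk1-Dio3) and 0.40 (Sfmbt2). At equal hemolysis index several lay nearer 0: -0.28 (red blood cell), -0.25 (mir-17-92), 0.56 (mir-34), 0.30 (epithelium), 0.31 (Dlk1-Dio3) and 0.13 (Sfmbt2). The myeloid list lay farther from 0, at -0.14. Of the 17 lists 0 passed the exact permutation test after adjustment, and 2 had an unadjusted p under 0.05. Several differences depended on single wild-type mice. They were nearer 0 without replicate 2, the mouse with the highest hemolysis index (7.82 cycles): they were -0.20 (let-7), 1.29 (skeletal and heart muscle), -0.31 (red blood cell), -0.20 (mir-17-92), 0.54 (mir-34), 0.055 (epithelium) and 0.043 (Dlk1-Dio3). They were farther from 0 without replicate 1, at -1.24 (red blood cell), -1.13 (mir-17-92), 1.63 (mir-34), 0.77 (epithelium) and 2.03 (Dlk1-Dio3), and let-7 was at -1.26 without replicate 3.

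**Figure D3:**
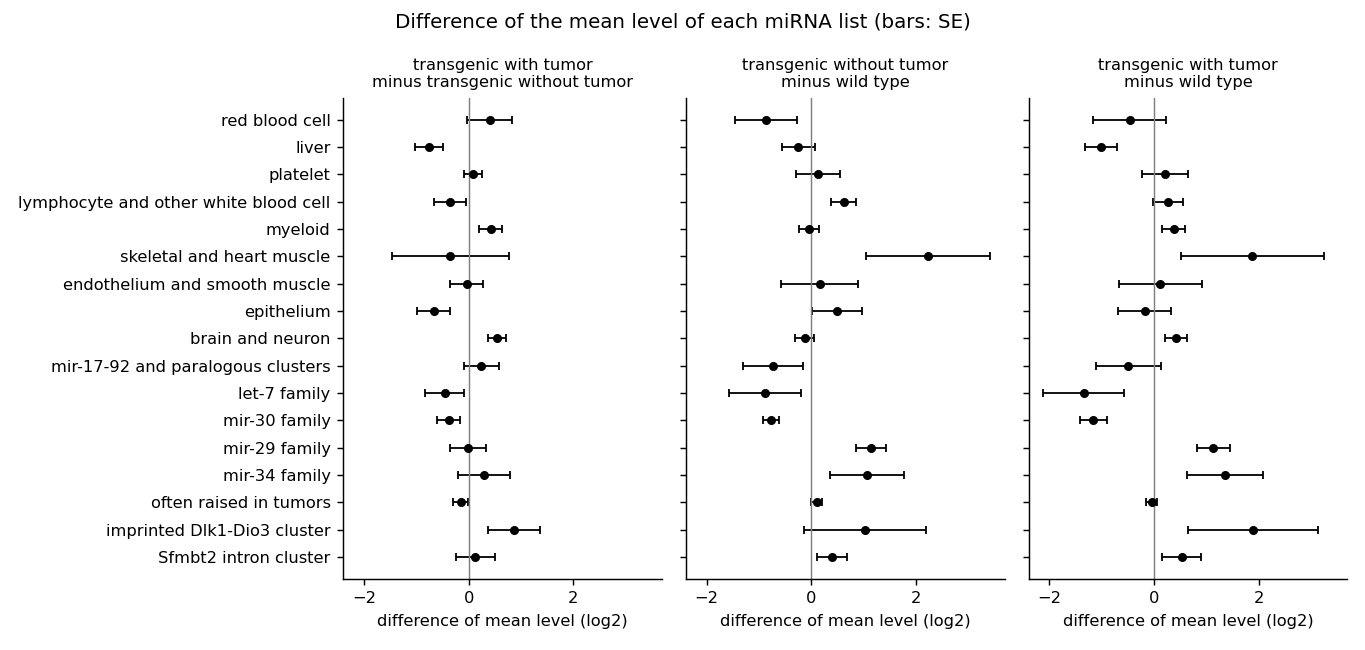
Difference of the mean level (log2) of each of the 17 miRNA lists in the 3 comparisons, with SE bars. The liver list lies at -0.76 between tumor and tumor-free mice and at -1.01 between tumor and wild-type mice, and the mir-29 family lies at 1.14 and 1.13 against wild type with the panel mean as the scaling, and below 0 with spike-ins.

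Tumor mice differed from wild-type mice in 28 of 338 assays, 14 higher and 14 lower, with 85 at an unadjusted p under 0.05. Liver miRNAs were again among those lower: miR-802-5p fell by 2.26 (SE 0.48, adjusted p = 0.00776, 7 of 7 below all wild-type mice), its rat assay by 3.76 (adjusted p = 0.00193), miR-192-3p by 2.37 (SE 0.48, adjusted p = 0.00776), miR-192-5p by 1.57 (adjusted p = 0.0199), miR-194-5p by 2.56 (adjusted p = 0.019) and miR-101b-3p by 1.57 (adjusted p = 0.0263). miR-455-3p fell by 3.54 (SE 0.75, 11.6-fold lower, adjusted p = 0.00776) and the rat assay miR-352 by 3.75 (adjusted p = 0.01). Both arms of miR-31, an epithelial miRNA, were lower, miR-31-3p by a difference of -2.15 and miR-31-5p by -2.03 (both adjusted p = 0.0275). miR-30e-3p (-1.59), let-7f-5p (-3.11), miR-196b-5p (-1.82) and the leukocyte miRNA miR-142-3p (-3.91) completed the lower set. The other arm of the last, miR-142-5p, did not pass and differed the other way, though not with raw Ct or spike-ins.

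The miRNAs that rose in tumor against wild-type mice included 2 neighbours on the X chromosome, miR-500-3p at 2.12 (SE 0.41, adjusted p = 0.00776, 7 of 7 above all wild-type mice) and miR-362-3p at 1.54 (adjusted p = 0.0275). miR-2137 differed by 3.48 (SE 0.72, 11.2-fold higher, adjusted p = 0.00776), miR-503-5p by 2.79 (adjusted p = 0.00824), miR-326-3p by 2.56 (adjusted p = 0.0159) and miR-1900 by 3.35 (SE 0.79, 10.2-fold higher, adjusted p = 0.0159). miR-300-3p (2.64) and miR-495-3p (2.51), both of the imprinted Dlk1-Dio3 cluster, rose, as did miR-128-3p (2.20), miR-125b-2-3p (4.32), the rat assay miR-338-3p (2.55), miR-29a-3p (1.63), miR-146a-5p (2.22) and the neutrophil miRNA miR-223-3p (1.96). Their adjusted p lay between 0.019 and 0.0459. Not passing were miR-21a-5p at 1.20 (adjusted p = 0.0668), miR-122-5p at -1.75 (0.136), miR-23a-3p at 1.20 (0.141), miR-155-5p at 1.42 (0.22), miR-34a-5p at 0.98 (0.258), miR-16-5p at -0.90 (0.353), miR-150-5p at 0.76 (0.639) and miR-451a at -0.43 (0.754).

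The balance of higher and lower calls depended on the scaling: raw Ct gave 0 higher and 15 lower, spike-ins 0 and 25, reference miRNAs 8 and 3, the median 18 and 13, and the plate sets 14 and 19. Of the 28, the rat miR-802-5p, the rat miR-352 and let-7f-5p kept their calls with reference miRNAs, raw Ct and spike-ins alike. Exact permutation per assay gave 0 calls (45 at an unadjusted p under 0.05, smallest adjusted p 0.201), a fit of only these 2 groups gave 1, and the count was 13 without wild-type replicate 2, 10 without wild-type replicate 3, 16 without tumor replicate 2 and 43 without tumor replicate 4. With the hemolysis index as a covariate, let-7f-5p, miR-196b-5p, miR-142-3p, miR-29a-3p, miR-146a-5p, miR-223-3p and miR-495-3p lost their calls. Without each sample in turn these were kept in 6, 5, 4, 7, 4, 13 and 6 of 17 fits, and miR-142-3p and miR-300-3p were lost with missing values set to Ct 37. miR-125b-2-3p was lost with a limit of Ct 35, miR-192-5p with quantile scaling, miR-196b-5p with the median, and miR-196b-5p and miR-495-3p with trend and robust variance. Without the 2 samples of low U6 Ct the count was 29, of which 19 were among the 28, and miR-192-5p, miR-128-3p, miR-101b-3p, miR-31-5p, miR-362-3p, miR-30e-3p, miR-29a-3p, miR-146a-5p and miR-142-3p lost their calls.

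By list, liver miRNAs differed by -1.01 between tumor and wild-type mice (exact permutation p = 0.025, adjusted p = 0.213). Of 11 members, 4 passed lower over all assays, and 7 lower and 1 higher, miR-193b-3p (1.47), passed adjusted over the list alone. The mir-30 family differed by -1.16 (exact permutation p = 0.0167, adjusted p = 0.184), with 1 of 7 members lower over all assays and 2, miR-30a-3p and miR-30e-3p, adjusted over the list alone. The mir-29 family differed by 1.13 (exact permutation p = 0.0417) but by -0.25 with raw Ct and -0.24 with spike-ins, with 1 of 3 members higher over all assays and 1 adjusted over the list alone. The let-7 family differed by -1.35, with 1 of 9 members lower over all assays and 2, let-7f-5p and let-7a-5p, adjusted over the list alone. The Dlk1-Dio3 list differed by 1.89 (exact permutation p = 0.108), with 14 of 14 members above 0, 2 higher over all assays and 3, with miR-376a-3p, adjusted over the list alone. The hemolysis index differed by -1.63 cycles between tumor and wild-type mice (exact permutation p = 0.267). At equal index the differences were -1.30 (liver, permutation p = 0.0056, adjusted p = 0.0704), -0.85 (mir-30, permutation p = 0.006, adjusted p = 0.0704), 0.67 (mir-29), -0.67 (let-7) and 0.95 (Dlk1-Dio3). Without wild-type replicate 2 the let-7 and Dlk1-Dio3 lists differed by -0.66 and 0.92, the skeletal and heart muscle list by 0.94 and the mir-34 family by 0.83. Without wild-type replicate 1 the last 3 differed by 2.90, 2.65 and 1.91, and let-7 differed by -1.73 without wild-type replicate 3.

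Blood cell lists held single members that moved apart. The myeloid list differed by 0.37, with miR-223-3p higher and miR-142-3p lower over all assays (both calls lost with the hemolysis covariate), and 3 higher and 1 lower adjusted over the list alone. The white blood cell list differed by 0.26, with 1 member higher and 1 lower by either count, and the platelet list by 0.20, with 1 higher by either count. The brain and neuron list differed by 0.42, with 1 of 6 members higher over all assays and 2, miR-128-3p and miR-138-5p, adjusted over the list alone. The epithelium list differed by -0.18 and the list often raised in tumors by -0.05, each with 1 member lower by either count, miR-31-5p. The others differed by -0.47 (red blood cell), 1.88 (skeletal and heart muscle), 0.12 (endothelium and smooth muscle), -0.49 (mir-17-92), 1.36 (mir-34) and 0.53 (Sfmbt2), with no member passing either way. At equal hemolysis index 4 lists changed sign: red blood cell (0.32), platelet (-0.16), endothelium and smooth muscle (-0.53) and mir-17-92 (0.15). There the skeletal and heart muscle list fell to 0.34 (SE 1.05), the mir-34 family to 0.68 (SE 0.53) and the Sfmbt2 list to 0.18. Of the 17 lists 0 passed the exact permutation test after adjustment, and 3 had an unadjusted p under 0.05.

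Detection of single miRNAs was compared by exact tests that leave little room to pass: 7 of 7 against 0 of 7 mice gives an exact p of 0.000583 and 7 of 7 against 0 of 3 an exact p of 0.00833, so 1 such assay alone could not pass after adjustment. By Fisher's exact test, 0 of 100 assays differed between tumor and tumor-free mice, 0 of 62 between tumor-free and wild-type mice and 0 of 94 between tumor and wild-type mice, with 0 at an unadjusted p under 0.05 in each and smallest exact p of 0.192, 0.2 and 0.3. The smallest p between tumor and tumor-free mice belonged to assays such as miR-202-5p and miR-708-5p, detected in 4 of 7 tumor mice and 7 of 7 tumor-free mice.

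The control assays included 3 small nuclear RNAs, which are nuclear and not miRNAs. RNU1A1 had a lower Ct, so more RNA, in tumor-free transgenic than in wild-type mice by a difference of -6.54 cycles (exact permutation p = 0.00833, adjusted p = 0.1 over 24 tests), and RNU5G differed by -3.58 cycles (exact permutation p = 0.0333, adjusted p = 0.198). U6 snRNA differed by 0.38 cycles. Of the 24 tests of control assays 0 passed after adjustment, and 4 had an unadjusted exact p under 0.05.

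**Figure D4:**
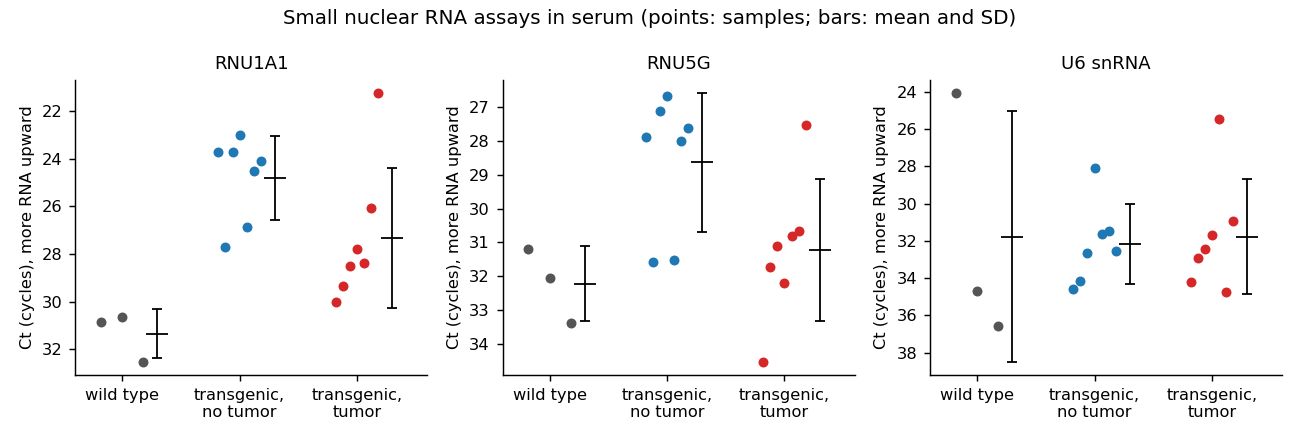
Ct (cycles, axis inverted so that more RNA lies upward) of the small nuclear RNA assays RNU1A1, RNU5G and U6 in each mouse, by group, with bars for mean and SD. RNU1A1 was at 24.8 ± 1.78 in tumor-free transgenic mice, 27.3 ± 2.96 in tumor mice and 31.3 ± 1.04 in wild-type mice.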

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

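The tests of red blood cell lysis and of normalization for the liver list, all tests on RNU1A1, RNU5G and miR-1900 were chosen after the results were seen; the other splits of the samples and the random lists matched on level were planned.

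Other splits of the same mice tested whether the counts of miRNAs could arise by chance. Between tumor and tumor-free mice, 2 of 100 splits, the real one included, gave as many as the real 5, and the highest other gave 18. Between tumor-free and wild-type mice, 1 of 100, the real one, gave as many as 2, and the highest other gave 0. Between tumor and wild-type mice, 3 of 100 gave as many as 28, and the highest other gave 78. Each share lay under 0.05, the level set beforehand, but the 3 shares were not adjusted and rest on 100 splits each. Chance is thus less likely but not excluded: other splits gave up to 18 and 78. Between tumor and tumor-free mice, exact permutation per assay gave 0 calls (smallest adjusted p 0.0591). No exact p of 7 against 7 mice can lie below 0.000583, so 1 assay alone could not pass over 338. This 0 therefore says little about chance. The split that gave 78, wild-type replicates 1 and 3 with tumor replicates 1, 2, 5, 6 and 7 against the rest, had the largest difference in hemolysis index of the 100 splits (-3.50 cycles), so a structure of the samples that follows this index stays open. With the index as a covariate, 26 miRNAs differed between tumor and wild-type mice, of which 21 were among the 28.

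The mean level of liver-rich miRNAs differed between tumor and tumor-free mice by -0.76 (exact permutation p = 0.0181, not passing after adjustment). A difference in red blood cell lysis as the cause is argued against by a difference of -0.83 (SE 0.23) at equal hemolysis index. That fit took 1 slope for all groups, although the list's r with the index was -0.92 in tumor-free and -0.39 in tumor mice. The index also follows miR-23a-3p, so an equal index need not mean equal lysis. Random lists matched on level had a mean difference of -0.00055, and the liver list lay at percentile 0.01 of 10000 such lists. This argues against an effect common to miRNAs of the same level. Members were drawn singly, without the correlation among liver miRNAs, so the percentile may overstate how rare the difference is. The choice of normalization stays open, because with spike-ins the difference was -0.90 with an SE of 0.71, so it lies within 2 SE of 0, although it was below 0 with all 6 scalings. A biological cause, such as the tumors, was not tested.

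RNU1A1 and RNU5G had a lower Ct in tumor-free transgenic than in wild-type mice, in assays outside the miRNA comparisons: RNU1A1 by a difference of -6.54 cycles and RNU5G by -3.58, and in tumor mice RNU1A1 differed by -4.02 (exact permutation p = 0.0417) but RNU5G by -0.99 (exact permutation p = 0.45), so a shift of both in both transgenic groups is not shown. More total serum RNA is argued against, since the mean miRNA Ct differed by 1.02 cycles (SE 0.92), the other way. The efficiency of extraction or cDNA synthesis is argued against less clearly: the largest fall among 4 spike-ins was -0.38 cycles (UniSp4, SE 0.32). The lowest bound, -1.50 cycles for cel-miR-39-3p (its difference less 2 SE), lay only slightly above the difference of RNU5G plus 2 SE. Blood cells or nuclei carried into the serum stay open: U6 snRNA differed by 0.38 cycles with an SE of 3.97, set by wild-type replicate 1 at 24.1 cycles (without it -3.47, exact permutation p = 0.0833), and the white blood cell list differed by 0.61 (exact permutation p = 0.0667). A difference in handling between wild-type and transgenic mice and an effect of the transgene were not tested and cannot be separated here, since the labels give no batch. Any of these may be the cause.

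miR-1900 was higher in tumor-free transgenic than in wild-type mice by 5.74. A difference in red blood cell lysis is argued against by a difference of 5.49 (SE 0.90) at equal hemolysis index. That index also follows miR-23a-3p, so an equal index need not mean equal lysis. RNA from the same source as RNU1A1 stays open: within groups the correlation was r = 0.19 (permutation p = 0.566; rho = 0.17, permutation p = 0.523; r = 0.36 without the 2 farthest samples), and the slope of 0.14 had a 95% interval from -0.30 to 0.59. The slope that the group difference needs is 0.76 (SE 0.13), and although the interval lies below 0.76, it does not lie below 0.76 less 2 SE, a margin that was added after the first comparison had excluded this source. An effect of the transgene may be the cause and was not tested apart from handling.

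Single samples stood far from the others of their group of 7 in 20 of 264 groups tested (7.58%), where chance alone gives about 5%. Among the controls, U6 snRNA had a Ct of 25.5 in tumor replicate 5, the sample whose label carries a question mark, and tumor-free replicate 2 had UniSp2 at 21.1 and UniSp4 at 27.4. UniSp6 differed by -0.34 cycles between tumor and wild-type mice (exact permutation p = 0.00833, adjusted p = 0.1). Among the tumor mice, replicate 4 had a platelet list level of 0.81, replicate 6 a white blood cell list level of 1.77, replicate 1 miR-101a-3p at 2.23, replicate 2 miR-141-3p at -1.55, and replicate 5 miR-126a-3p at 0.95 and miR-326-3p at 1.60. In tumor-free replicate 7, miR-155-5p was at -1.83, the rat assay miR-338-3p at 0.49 and miR-146a-5p at 4.38. Replicate 1 of that group had miR-326-3p at -2.86, miR-362-3p at -0.27 and miR-30e-3p at 0.57, and replicate 2 had let-7a-5p at 3.97. In replicate 4, miR-196b-5p was at -6.61 and miR-30a-5p at 0.15, and in replicate 5, miR-34a-5p was at -1.11 and miR-467a-5p at -6.52.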

How the results depend on the processing

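Scaling per plate set, leaving out both samples of low U6 Ct, and, for the lists, raw Ct, spike-ins and the hemolysis covariate with its permutation test were chosen after the data were seen, as was leaving out samples for the control assays. A detection limit of Ct 40 equals the one used, since no value lies at or above 37. No paired analysis was run because the labels give no shared replicate numbers with a stated meaning, and with the number in the animal label as a random block (correlation 0.07) the counts were 6, 3 and 28. Each call of the 3 comparisons (5, 2 and 28) kept its direction in all settings that gave a value. Without each sample in turn, 2 of 5, 1 of 2 and 6 of 28 calls were kept every time. Counts of Fisher's exact test and of lists that passed stayed at 0 in all their settings, for the lists with a smallest adjusted p of 0.0704 at equal hemolysis index. Fisher's tests, and list tests against 3 wild-type mice, leave little room to pass, so 0 there does not show stability. Between tumor and tumor-free mice, the count of 5 became 0 with reference miRNAs, raw Ct, spike-ins or exact permutation, 9 with quantile scaling (252 assays tested), 8 with only the 2 groups, 13 with the hemolysis covariate, 10 without the 2 samples of low U6 Ct, and 2 to 10 without each sample. Between tumor-free and wild-type mice, the count of 2 became 1 with median, reference miRNA or quantile scaling or with trend and robust variance, 0 with raw Ct or exact permutation, 7 with scaling per plate set, 4 with missing values set to Ct 37 under either filter, 15 with only the 2 groups, 5 with the hemolysis covariate, 8 without the 2 samples of low U6 Ct, and 1 to 9 without each sample. The other counts that moved were 6 without tumor-free replicate 1 or tumor replicate 5, 4 without tumor replicate 1 and 5 without tumor replicate 4. Between tumor and wild-type mice, the count of 28 became 11 with reference miRNAs, 15 with raw Ct, 1 with only the 2 groups, 0 with exact permutation, and 10 to 43 without each sample, and it was 29 without the 2 samples of low U6 Ct, of which 19 were shared. The cause was not tested. Of the single miRNAs and control assays in all settings, 7430 values kept direction and side of the threshold, 295 lost and 135 gained a call, and of the list values 1228 kept both. Only the calls of the main fit (5, 2 and 28) could be lost, and the 7430 include values that passed on neither side. The 295 set against the 7430 therefore does not measure how stable the calls are. A further 361 values, of 122 results, changed sign or became 0. Of these, 0 passed the test with the main settings and 0 with the alternative, so no direction was established on either side, and the cause was not tested.

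These values are given as log2 differences, and as cycles for Ct and the hemolysis index. miR-451a (-0.30), miR-144-3p (-0.00018), miR-101a-3p (-0.29), miR-191-5p (-0.19), miR-30d-5p (-0.20), miR-29a-3p (-0.13), miR-34a-5p (-0.17), rno-miR-136-3p (-0.36), miR-297a-5p (-0.14), the platelet list (-0.28), the mir-17-92 and paralogous clusters list (-0.12), the mir-34 family list (-0.070) and the Sfmbt2 intron cluster list (-0.23) changed sign with raw Ct between tumor and tumor-free mice. miR-24-3p (-0.86), miR-29b-3p (-0.061), miR-142-5p (-0.10), miR-21a-5p (-0.71), miR-23a-3p (-0.29), miR-206-3p (-1.08), miR-145a-5p (-0.60), miR-141-3p (-0.84), miR-219a-5p (-0.80), miR-138-5p (-0.022), miR-34a-5p (-0.23) and miR-434-3p (-0.30) changed sign with raw Ct between tumor-free and wild-type mice. miR-297a-5p (-0.43), miR-669c-5p (-0.52), miR-127-3p (-1.63), miR-200b-5p (-0.75), the platelet list (-0.89), the lymphocyte and other white blood cell list (-0.41), the endothelium and smooth muscle list (-0.86), the epithelium list (-0.53), the often raised in tumors list (-0.91), the imprinted Dlk1-Dio3 cluster list (-0.0015) and the Sfmbt2 intron cluster list (-0.62) changed sign with raw Ct between tumor-free and wild-type mice. miR-24-3p (-0.71), miR-150-5p (-0.62), miR-29b-3p (-0.58), miR-142-5p (-0.52), miR-21a-5p (-0.18), miR-23a-3p (-0.18), miR-1a-3p (-0.26), miR-206-3p (-0.58), miR-143-3p (-0.49) and miR-145a-5p (-1.30) changed sign with raw Ct between tumor and wild-type mice. miR-200b-3p (-1.28), miR-200a-3p (-0.51), miR-132-3p (-1.02), miR-29c-3p (-0.43), miR-34a-5p (-0.40), miR-449a-5p (-0.72), miR-210-3p (-1.14), miR-297a-5p (-0.57), miR-669c-5p (-0.37) and miR-134-5p (-0.013) changed sign with raw Ct between tumor and wild-type mice. The platelet list (-1.18), the lymphocyte and other white blood cell list (-1.12), the myeloid list (-1.01), the endothelium and smooth muscle list (-1.26), the brain and neuron list (-0.96), the mir-29 family list (-0.25), the mir-34 family list (-0.025) and the Sfmbt2 intron cluster list (-0.86) changed sign with raw Ct between tumor and wild-type mice. miR-451a (-0.069), miR-101a-3p (-0.066), rno-miR-136-3p (-0.13), the platelet list (-0.054) and the Sfmbt2 intron cluster list (-0.0042) changed sign with spike-ins between tumor and tumor-free mice. miR-24-3p (-1.08), miR-29b-3p (-0.28), miR-142-5p (-0.32), miR-21a-5p (-0.93), miR-23a-3p (-0.51), miR-206-3p (-1.14), miR-143-3p (-0.14), miR-145a-5p (-0.82), miR-141-3p (-1.06) and miR-200b-3p (-0.19) changed sign with spike-ins between tumor-free and wild-type mice. miR-200a-3p (-0.025), miR-219a-5p (-1.02), miR-138-5p (-0.24), miR-29c-3p (-0.17), miR-34a-5p (-0.45), miR-434-3p (-0.51), miR-297a-5p (-0.64), miR-669c-5p (-0.74), miR-127-3p (-1.69) and miR-200b-5p (-0.81) changed sign with spike-ins between tumor-free and wild-type mice. The platelet list (-1.11), the lymphocyte and other white blood cell list (-0.62), the endothelium and smooth muscle list (-1.08), the epithelium list (-0.75), the mir-29 family list (-0.095), the mir-34 family list (-0.17), the often raised in tumors list (-1.13), the imprinted Dlk1-Dio3 cluster list (-0.22) and the Sfmbt2 intron cluster list (-0.84) changed sign with spike-ins between tumor-free and wild-type mice. miR-24-3p (-0.70), miR-150-5p (-0.61), miR-29b-3p (-0.57), miR-142-5p (-0.51), miR-21a-5p (-0.17), miR-23a-3p (-0.17), miR-1a-3p (-0.25), miR-206-3p (-0.42), miR-143-3p (-0.48) and miR-145a-5p (-1.29) changed sign with spike-ins between tumor and wild-type mice. miR-200b-3p (-1.27), miR-200a-3p (-0.50), miR-132-3p (-1.01), miR-29c-3p (-0.42), miR-34a-5p (-0.39), miR-449a-5p (-0.71), miR-210-3p (-1.13), miR-297a-5p (-0.56), miR-669c-5p (-0.36) and miR-410-3p (-0.068) changed sign with spike-ins between tumor and wild-type mice. The platelet list (-1.17), the lymphocyte and other white blood cell list (-1.11), the myeloid list (-0.997), the endothelium and smooth muscle list (-1.25), the brain and neuron list (-0.95), the mir-29 family list (-0.24), the mir-34 family list (-0.016) and the Sfmbt2 intron cluster list (-0.85) changed sign with spike-ins between tumor and wild-type mice. miR-142-5p (0.067), miR-34c-5p (-0.58) and the platelet list (-0.012) changed sign with the hemolysis index as a covariate between tumor and tumor-free mice. miR-451a (0.29), miR-24-3p (-0.12), miR-206-3p (-0.82), let-7g-5p (0.39), let-7c-5p (0.22), miR-30b-5p (0.017), miR-449a-5p (0.57), miR-434-3p (-0.080), miR-127-3p (-0.64), the platelet list (-0.15) and the endothelium and smooth muscle list (-0.33) changed sign with the hemolysis index as a covariate between tumor-free and wild-type mice. miR-451a (0.61), miR-144-3p (0.45), miR-25-3p (0.20), miR-191-5p (0.16), miR-133b-3p (-0.058), miR-1a-3p (-0.83), miR-206-3p (-0.43) and miR-145a-5p (-0.30) changed sign with the hemolysis index as a covariate between tumor and wild-type mice. miR-141-3p (0.068), miR-200b-3p (-0.67), miR-93-5p (0.18), let-7i-5p (0.71), the red blood cell list (0.32), the platelet list (-0.16), the endothelium and smooth muscle list (-0.53) and the mir-17-92 and paralogous clusters list (0.15) changed sign with the hemolysis index as a covariate between tumor and wild-type mice. miR-451a (-0.24), miR-101a-3p (-0.24), miR-191-5p (-0.14), miR-30d-5p (-0.14), miR-29a-3p (-0.074), miR-34a-5p (-0.11), rno-miR-136-3p (-0.24), miR-297a-5p (-0.085), the platelet list (-0.23), the mir-17-92 and paralogous clusters list (-0.064), the mir-34 family list (-0.015) and the Sfmbt2 intron cluster list (-0.18) changed sign with reference miRNAs between tumor and tumor-free mice. miR-122-5p (0.37), miR-126a-3p (0.018), miR-191-5p (0.29), let-7g-5p (0.35), let-7c-5p (0.38), miR-30b-5p (0.27), miR-449a-5p (0.29), miR-467a-5p (0.38), the liver list (0.24), the myeloid list (0.45) and the brain and neuron list (0.37) changed sign with reference miRNAs between tumor-free and wild-type mice. miR-191-5p (0.16), miR-141-3p (0.028), miR-219a-5p (0.18), the epithelium list (0.0056) and the often raised in tumors list (0.14) changed sign with reference miRNAs between tumor and wild-type mice. miR-451a (-0.013), miR-133b-3p (0.30), miR-133a-3p (0.12), miR-145a-5p (0.073), miR-126a-5p (0.075), miR-467a-5p (0.14), Ct of U6 snRNA (0.67) and the endothelium and smooth muscle list (0.071) changed sign without the 2 samples of low U6 Ct between tumor and tumor-free mice. miR-122-5p (0.42), miR-467a-5p (0.080), Ct of U6 snRNA (-3.47) and the myeloid list (0.091) changed sign without the 2 samples of low U6 Ct between tumor-free and wild-type mice. miR-141-3p (0.020), miR-219a-5p (0.031), miR-210-3p (-0.0087), miR-467a-5p (0.22), Ct of U6 snRNA (-2.80) and the epithelium list (0.22) changed sign without the 2 samples of low U6 Ct between tumor and wild-type mice. miR-451a (0), miR-16-5p (0), miR-144-3p (-0.14), miR-23a-3p (-0.31), miR-133b-3p (0.12) and miR-93-5p (-0.056) changed sign with quantile scaling between tumor and tumor-free mice. miR-451a (0.23), miR-122-5p (0.56), miR-141-3p (-0.077), let-7g-5p (0.67), let-7c-5p (0.0028) and miR-30b-5p (0.38) changed sign with quantile scaling between tumor-free and wild-type mice. miR-451a (0.23), miR-191-5p (0.076) and miR-219a-5p (0.15) changed sign with quantile scaling between tumor and wild-type mice. miR-142-5p (0.064), miR-133b-3p (0.10), miR-29c-3p (0.0058), the endothelium and smooth muscle list (0.083) and the mir-29 family list (0.11) changed sign with median scaling between tumor and tumor-free mice. miR-191-5p (0.079), miR-219a-5p (0.10) and the often raised in tumors list (0.063) changed sign with median scaling between tumor and wild-type mice. The often raised in tumors list (0.29) changed sign with a limit of Ct 35 between tumor and tumor-free mice. miR-467a-5p (0.34), the brain and neuron list (0.41) and the often raised in tumors list (-0.50) changed sign with a limit of Ct 35 between tumor-free and wild-type mice. miR-451a (-0.00042) and miR-126a-5p (0.013) changed sign with scaling per plate set between tumor and tumor-free mice. The often raised in tumors list (0.30) changed sign with only members detected in all samples between tumor and tumor-free mice. The often raised in tumors list (-0.50) changed sign with only members detected in all samples between tumor-free and wild-type mice. The hemolysis index (0.065) changed sign with miR-451a set against the panel mean between tumor and tumor-free mice. miR-34c-5p (-0.22) changed sign with a minimum of 3 detections in any group between tumor and tumor-free mice. miR-34c-5p (-0.22) changed sign with missing values set to Ct 37 between tumor and tumor-free mice.

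Lowest and highest values without each sample in turn are given for results that changed sign in 1 or more of these settings. miR-451a (-0.28 to 0.33), miR-101a-3p (-0.057 to 0.26), miR-142-5p (-0.31 to 0.14), miR-133b-3p (-0.80 to 0.37), miR-133a-3p (-1.01 to 0.23), miR-206-3p (-0.069 to 1.38) and miR-145a-5p (-0.58 to 0.074) spanned 0 between tumor and tumor-free mice. miR-126a-5p (-0.29 to 0.077), miR-141-3p (-0.46 to 0.065), miR-29c-3p (-0.23 to 0.11), miR-34a-5p (-0.031 to 0.40), miR-34c-5p (-0.068 to 0.94), rno-miR-136-3p (-0.20 to 0.52) and miR-297a-5p (-0.15 to 0.59) spanned 0 between tumor and tumor-free mice. miR-467a-5p (-0.63 to 0.15), Ct of U6 snRNA (-1.06 to 0.67), the skeletal and heart muscle list (-1.001 to 0.044), the endothelium and smooth muscle list (-0.19 to 0.15), the mir-29 family list (-0.16 to 0.15) and the Sfmbt2 intron cluster list (-0.063 to 0.34) spanned 0 between tumor and tumor-free mice. miR-451a (-0.997 to 0.026), miR-122-5p (-0.58 to 0.42), miR-24-3p (-0.15 to 0.40), miR-191-5p (-0.39 to 0.14), miR-206-3p (-2.40 to 3.88), miR-141-3p (-0.0096 to 0.35), let-7g-5p (-0.58 to 0.32) and let-7c-5p (-0.39 to 0.30) spanned 0 between tumor-free and wild-type mice. miR-449a-5p (-0.44 to 0.017), miR-434-3p (-0.76 to 1.87), miR-154-5p (-0.10 to 2.80), miR-466g (-1.67 to 0.014), miR-669c-5p (-0.14 to 0.86), miR-467a-5p (-0.45 to 0.33), miR-127-3p (-2.66 to 3.03) and miR-200b-5p (-0.56 to 2.70) spanned 0 between tumor-free and wild-type mice. The number of miRNA assays detected per sample (-4.43 to 3.07), Ct of U6 snRNA (-3.47 to 2.78), the platelet list (-0.22 to 0.48), the myeloid list (-0.13 to 0.091), the endothelium and smooth muscle list (-0.50 to 0.75) and the brain and neuron list (-0.25 to 0.026) spanned 0 between tumor-free and wild-type mice. miR-451a (-0.93 to 0.091), miR-144-3p (-1.43 to 0.25), miR-191-5p (-0.23 to 0.31), miR-206-3p (-1.55 to 4.73), miR-145a-5p (-0.22 to 0.49) and miR-141-3p (-0.36 to 0.24) spanned 0 between tumor and wild-type mice. miR-200b-3p (-0.77 to 0.92), miR-219a-5p (-0.14 to 0.12), let-7i-5p (-0.74 to 0.31), miR-466g (-1.20 to 0.48), miR-467a-5p (-0.69 to 0.036) and Ct of U6 snRNA (-3.85 to 2.39) spanned 0 between tumor and wild-type mice. The red blood cell list (-0.84 to 0.10), the platelet list (-0.14 to 0.56), the endothelium and smooth muscle list (-0.54 to 0.72), the epithelium list (-0.62 to 0.091), the mir-17-92 and paralogous clusters list (-0.89 to 0.038) and the often raised in tumors list (-0.094 to 0.0029) spanned 0 between tumor and wild-type mice.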

Other observations

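The grouping of miRNAs by gene cluster, its test and its other scalings were chosen after the result was seen.

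Of 10 clusters of neighbouring miRNA genes, 4 had an unadjusted exact p under 0.05 between tumor and tumor-free mice, and the other 6 differed by -0.67 to 0.13. The X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450b stood higher in tumor than in tumor-free mice by 0.96 (exact permutation p = 0.00524, adjusted p = 0.125 over 30 tests), with 8 of 8 assays above 0. The cluster of miR-500, miR-501, miR-362, miR-188 and miR-532 differed by 0.39 in this comparison (exact permutation p = 0.0326) and by 0.87 between tumor and wild-type mice (exact permutation p = 0.00833, adjusted p = 0.125, 8 of 9 assays above 0). The sensory cluster of miR-182, miR-96 and miR-183 differed by -1.25 between tumor and tumor-free mice (exact permutation p = 0.0338, adjusted p = 0.167). In it, miR-182-5p was detected in 5 of 7 tumor mice and 7 of 7 tumor-free mice. miR-183-5p was detected in 6 of 7 and 7 of 7, and miR-96-5p in 5 of 7 in both groups. The difference of this cluster may thus depend in part on how undetected values are treated. No other detection limit was tried for the clusters. The imprinted cluster from miR-411 to miR-410 differed by 1.00 between tumor and tumor-free mice (exact permutation p = 0.049, adjusted p = 0.167). Against wild type, the cluster of let-7d, let-7f-1 and let-7a-1 differed by -0.39 in tumor mice (exact permutation p = 0.0417). None of the 30 tests passed after adjustment. Between tumor and tumor-free mice the directions of these 4 clusters were the same with 5 other scalings, from 0.59 to 1.08 for the first, from 0.028 to 0.51 for the second, from -1.61 to -1.13 for the third and from 0.64 to 1.12 for the fourth. Between tumor and wild-type mice the second cluster turned to -0.51 with raw Ct and -0.50 with spike-ins, so its direction there depends on the scaling.

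A hypothesis is that serum levels keep the shared transcription of neighbouring miRNA genes. Over 10 clusters of at least 3 genes (58 assays), the mean within-group correlation between assays of different genes was 0.43, at percentile 100 of 10000 random reassignments of genes to clusters, whose highest was 0.28. At equal hemolysis index it was 0.29, against a highest of 0.17. The first version of this test also counted pairs of arms of 1 gene and gave the same percentile; those pairs were then left out. For single clusters the mean correlation was taken over all pairs of assays, pairs of arms of 1 gene included. It ran from -0.10 (let-7d, let-7f-1 and let-7a-1) to 0.78 (miR-429, miR-200a and miR-200b). The reassignments were not matched on level. Mean cluster levels in tumor mice ran from -5.79 (miR-182, miR-96 and miR-183) to 2.37 (miR-25, miR-93 and miR-106b). The test does not separate shared transcription, which may be the cause, from release by a shared cell type, from similar sequences or from a similar level of the members.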
